A study of Mus musculus with 2 samples.

How the data were processed

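H3K36me3 was measured by ChIP-seq in embryonic day 15.5 mouse hindbrain, in 2 biological replicates of 3 technical replicates each. Per the file headers, replicate 1 came from 78 embryos and replicate 2 from 62. The deposited files were peak lists in narrowPeak format on mm10, with 1 list for each replicate, 1 for both replicates pooled and 1 of replicated peaks. In each list the deposited signal value is a ratio, the fold of ChIP over control made by the authors. Each list also holds the −log10 p and the −log10 q of every peak, both computed by the authors. Per the file headers, the peaks of replicate 1 derive from its alignments and 2 other files, and those of replicate 2 from its alignments and 1 other file. The pooled peaks derive from both alignments and 2 other files. These other files were taken to be controls. The aligner, the peak caller, its threshold and the rule that keeps a pooled peak as replicated are not given in the sources used here. The lowest −log10 p was 2.01 in replicate 1 and 2.03 in the pooled peaks. No read counts were given, so the depth behind each peak is unknown and no counting interval can be had.

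Overlapping peaks were merged for covered length. Genes were the 21938 protein-coding genes of chromosomes 1 to 19, X and Y in GENCODE M21. Shares of the genome were taken over 2648 Mb of sequenced bases on those 21 chromosomes, and peaks on other scaffolds were left out of all gene values. Covered base pairs were assigned to gene bodies, exons, introns, promoters (1 kb either side of the gene start), other annotated genes and the remainder. A gene was called marked when replicated peaks covered at least 10% of its span. Profiles used 10 equal parts of marked genes of at least 5 kb, with 95% intervals from 1000 bootstrap draws over genes. Gene ends used 500 bp windows in marked genes of at least 20 kb with no other protein-coding gene within 10 kb. Domains joined replicated peaks across gaps of up to 3 kb. Values over the replicates are the mean and the SD with n = 2.

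Chance overlap of the replicates came from 100 random placements of the peaks on the same chromosome. Each of 34 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists at 0.05. Each list was also compared with 10000 random lists and 100000 permutation draws matched on 10 groups of gene length. X genes were compared with autosomal genes by Fisher's exact test, two-sided. The difference between the replicates has 1 library per side and no test. Genes marked in 1 replicate alone were compared with the lists by Fisher's exact test, adjusted over the lists with a member marked in either replicate. The random seed was 1.

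The lists covered ribosomal proteins, the proteasome, RNA polymerase II and elongation factors, the spliceosome, H3K36 methylation writers, erasers and readers, pan-neuronal genes, neural progenitors and radial glia, granule neuron progenitors and the rhombic lip, and Purkinje cells and the cerebellar ventricular zone. They also covered glutamatergic, GABAergic and glycinergic transmission, monoaminergic neurons, cranial motor neurons, Hox paralog groups 1 to 5 and 9 to 13, and forebrain and midbrain regulators. Lists of other cell types held oligodendrocytes, astrocytes, microglia and macrophages, endothelial cells and pericytes, erythroid cells, meninges and mesenchyme, choroid plexus, peripheral sensory neurons and Schwann cells, liver, striated muscle and heart, and epidermis. The last held the cell cycle, replication-dependent histones, numbered Zfp genes, olfactory receptors, clustered protocadherins, imprinted genes, and long neuronal adhesion and ion channel genes. Of their symbols 5 were not found, namely Whsc1, Whsc1l1, Ahsp, Drgx and Peg13.

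The lists, the covered share, the tests and the rule for named genes were set before the data were examined. The rule named the 10 genes of at least 5 kb with the largest covered share that overlap no other protein-coding gene, and the gene with the most overlap under each of the 10 longest domains. It also named the 2 highest and 2 lowest members of each list, the 3 genes of at least 5 kb with the largest difference between the replicates each way, and all members of the writers, erasers and readers list and of Hox groups 1 to 5. Where a list held more than 2 unmarked members at 0%, the longer genes were named. The map of Setd2 was chosen by its function. Neighbouring genes were named after their values were seen.

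The alternatives were each replicate's own peaks, the pooled peaks, the stronger peaks by fold (at or above the file's median), peaks with q of at most 0.01, covered shares of 5%, 20% or 1 bp, genes that overlap no other, spans without the first 1 kb, genes of at least 5 kb or 20 kb, promoters of 2 kb, gaps of 1 kb and 10 kb, an overlap of 50%, equal numbers of the strongest peaks, and length-matched permutation. Those added after the data were seen were a background without chemosensory receptors, placement inside genes, the last 50% of the gene, peaks that overlap a peak of each replicate by 50%, equal covered length, and peak counts without scaffolds. No deposited peak list was left out.

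The code used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1. It was tested on simulated data. Covered length was the same as that of bedtools in 1732 of 1732 intervals. All 119 planted marked genes were called and no other, 17 of 17 planted lists were called, and 1 of 83 lists without a planted difference was called. The planted lists were all marked more often than other genes and were larger than most of the lists used here. The simulation therefore does not measure the power to call short lists or lists marked less often.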

Results

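Chromatin of the embryonic mouse hindbrain was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against histone H3 trimethylated at lysine 36 (H3K36me3), a modification that Setd2 places on nucleosomes as RNA polymerase II transcribes through a gene. The hindbrain comprises the developing cerebellum, pons and medulla. Tissue was taken at embryonic day 15.5 from mice of the B6NCrl strain and pooled over male and female embryos. There was 1 group with 2 biological replicates, replicate 1 from 78 embryos and replicate 2 from 62 embryos, and each replicate combined 3 technical replicates. No second tissue, stage or condition was included. The comparisons below are therefore between regions and gene groups within the hindbrain, and between the replicates. The files held peak positions with the authors' fold and p and q values. They gave no read counts, so the sequencing depth of each replicate is unknown.

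Peaks covered a small part of the genome in each replicate and were longer in total in replicate 1. Replicate 1 had 174650 peaks over 86.5 Mb, which was 3.27% of the sequenced genome, and replicate 2 had 136585 peaks over 61.0 Mb, which was 2.302%. The median peak width was 336 bp in replicate 1 and 325 bp in replicate 2, and the authors' median fold over control was 2.87 and 3.01. The peaks called by the authors on the pooled replicates numbered 164601 over 97.53 Mb, and their replicated peaks numbered 111282 over 83.9 Mb, or 3.17% of the genome, with a median width of 520 bp. All 111282 replicated peaks were also in the pooled file with the same position, fold, p and q. A peak of each replicate overlapped 84445 of them by 50% of either peak. The other 26837 did not meet that overlap, and 20813 replicated peaks touched no peak of replicate 2 and 6246 none of replicate 1. The replicated peaks were used below for the values over both replicates, with each replicate's own peaks beside them. By the authors' q, 8164 peaks of replicate 1, 15980 of replicate 2 and 1192 of the replicated peaks lay above 0.05.

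Most peaks of replicate 2 lay in regions marked in replicate 1, and genes ranked alike by covered share, which was higher on average in replicate 1 (12.2% against 8.85%). Of the peaks of replicate 2, 82.5% overlapped a peak of replicate 1 by at least 1 bp, and 58.7% of the peaks of replicate 1 overlapped one of replicate 2. The replicates shared 45.8 Mb, a Jaccard index of 45.1%. Placing the peaks of replicate 1 at random on their chromosomes gave a mean Jaccard index of 1.52% and a highest of 1.57% over 100 placements, and placing them only inside protein-coding genes gave a mean of 3.52% and a highest of 3.59%. Among the 10000 peaks with the lowest p in each replicate, 97.48% of those of replicate 1 and 98.8% of those of replicate 2 overlapped the other replicate. Peaks without an overlap were weaker and narrower, with a median fold of 2.64 against 3.12 and a median width of 250 bp against 459 bp in replicate 1, and 2.82 against 3.13 and 231 bp against 362 bp in replicate 2. Across 21938 protein-coding genes, which are not independent replicates, the share of the gene covered had a Pearson's r of 0.965 and a Spearman's rho of 0.949 between the replicates. Over the 11390 genes with a peak in either replicate these were 0.949 and 0.940.

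**Figure D1:**
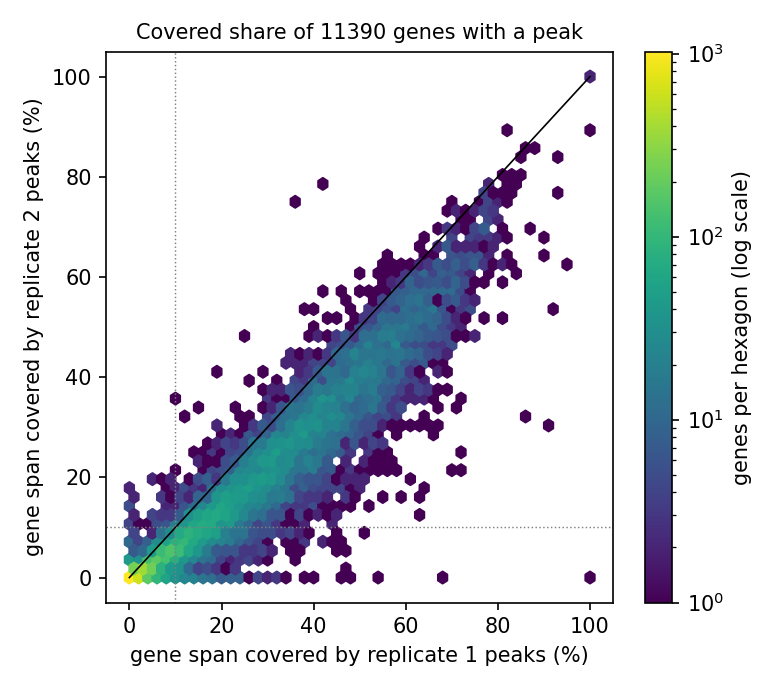
Share of each gene's span covered by the peaks of replicate 1 (x axis, %) and replicate 2 (y axis, %) for 11390 protein-coding genes with a peak in either replicate; colour gives the number of genes per hexagon on a log scale, the solid line marks equal shares and the dotted lines mark 10%. Most genes lie below the line of equal shares; replicate 1 covered 86.5 Mb and replicate 2 covered 61.0 Mb in total.

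H3K36me3 peaks lay almost wholly within protein-coding genes and were depleted at promoters. Gene bodies held 94.96% of the covered base pairs of the replicated peaks (94.7% ± 0.287, SD of the replicates, n = 2) and took 39.3% of the genome, a 2.42-fold excess. Exons held 19.6% (19.4% ± 0.551, n = 2) against 2.84% of the genome, a 6.91-fold excess, and introns held 75.3% against 36.4%, a 2.07-fold excess. Promoters, the 1 kb either side of the annotated gene start, held 0.383% (0.378% ± 0.0169, n = 2) against 1.56% of the genome, or 0.246 times their share. With 2 kb either side they held 1.29% against 3.08%. Annotated genes of other types outside protein-coding genes held 0.864% against 6.84%, and sequence outside annotated genes 4.17% against 53.9%. Each of these departures from the genome share was larger than the spread between the replicates.

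Within marked genes the mark was nearly absent at the start and rose towards the end. Over 6315 genes of at least 5 kb with at least 10% of the span covered, replicated peaks covered 3.69% of the first of 10 equal parts of the gene, 56.6% of the ninth part and 52.6% of the last. The last part was covered 14.3 times as much as the first (12.98 in replicate 1 and 14.2 in replicate 2 over the same genes). Among genes of at least 20 kb this ratio was 9.32. In replicate 1 the mean rose from 3.89% in the first part to 53.9% in the ninth, and in replicate 2 from 2.69% to 41.3%. The last part was covered more than the first in 5393 genes and less in 290. The first part held no peak at all in 5268 genes, and the last part held none in 765. Genes are not independent replicates, and the intervals in the plot of the profile come from resampling genes.

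**Figure D2:**
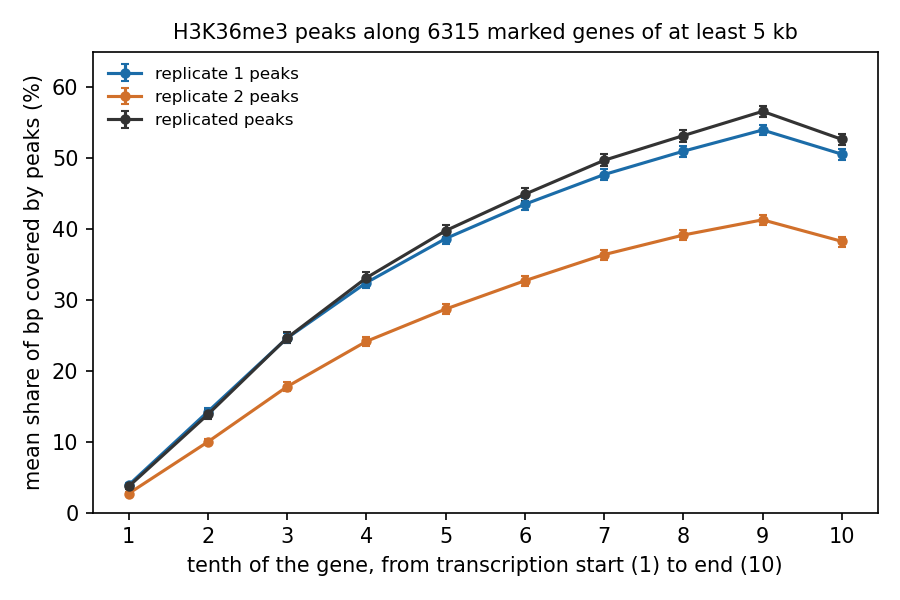
Mean share of base pairs covered by peaks (y axis, %) in 10 equal parts of the gene from transcription start to end (x axis) over 6315 marked genes of at least 5 kb; lines are replicate 1, replicate 2 and the authors' replicated peaks, and bars are 95% bootstrap intervals over genes. All 3 lines are lowest in the first part and highest in the ninth, at 53.9% in replicate 1, 41.3% in replicate 2 and 56.6% in the replicated peaks.

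The gap at the start and the reach beyond the end were measured on 890 marked genes of at least 20 kb with no other protein-coding gene within 10 kb. No base of the first 1000 bp after the start was covered by a replicated peak in any of them, and coverage reached 1.57% in the window from 1500 bp and 20.5% in the window from 9000 bp. Near the end, coverage was highest at 50.7% in the 500 bp window that begins 3000 bp before the annotated end. It was 28.6% in the last 500 bp of the gene, 32.2% in the first 500 bp beyond it, and 3.03% in the window from 4500 bp. Exons of marked genes were covered more than introns, 52.2% against 34.1% on average over 6257 genes, and exons had the larger share in 5021 of them. The ratio of the means was 1.53 (1.52 in replicate 1 and 1.56 in replicate 2). In the last 50% of the gene, a comparison chosen after the profile was seen, it was 1.22.

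Setd2 itself had the gap at the start, but not a steady rise towards the end. The gene, on the plus strand of chromosome 9 from 110532597 to 110618633 (mm10), was covered over 38.7% of its 86.0 kb by 42 replicated peaks, the first of them 14.7 kb downstream of the start. The first peak lay at 14.7 kb in replicate 1 as well, and at 6.95 kb in replicate 2.

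**Figure D3:**
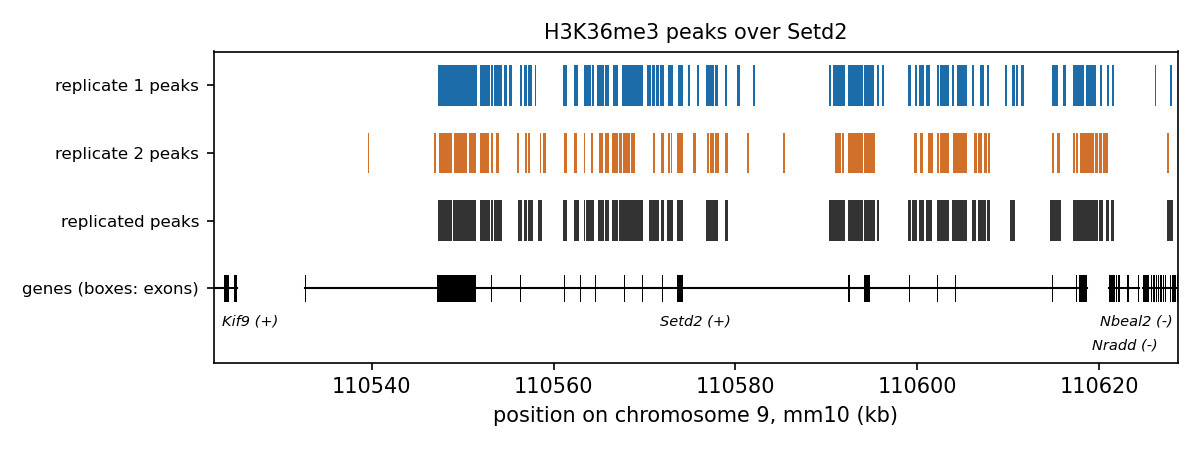
Peaks of replicate 1, replicate 2 and the authors' replicated set (rows) over Setd2 and 10 kb on either side, on chromosome 9 of mm10 (x axis, kb); black boxes are annotated exons and the strand stands beside each gene name. The gene holds 60 peaks in replicate 1, 56 in replicate 2 and 42 replicated peaks, and the first peak lies 14.7 kb from the start in replicate 1 and the replicated set and 6.95 kb in replicate 2.

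The most heavily marked genes were covered over most of their length. Among genes of at least 5 kb that overlap no other protein-coding gene, the highest was Sf3a1, a spliceosome subunit on chromosome 11 (4160350 to 4182541), with 87.7% (76.3% ± 4.29 over the replicates' own peaks, n = 2). Kpnb1, the nuclear import receptor importin beta, had 87.6%, and Trrap, a scaffold of histone acetyltransferase complexes that spans 92.0 kb, also had 87.6%. The zinc finger genes Zfp110 and Zfp606 followed with 87.3% and 86.6%. Rbm5, a splicing regulator, had 86.6%, Kmt2b, an H3K4 methyltransferase, 85.6% and Prr12 85.6%. Cct2, a chaperonin subunit, had 85.3%, and Glyr1, whose PWWP domain binds methylated H3K36, had 85.2%. Joining peaks across gaps of up to 3 kb gave 20423 domains with a median length of 2.62 kb, of which 4349 were at least 10 kb and 185 at least 50 kb. The longest, 139 kb on chromosome 4 (145051437 to 145190531), lay inside Vps13d, a lipid transfer protein gene, and peaks covered 76.2% of it. The next lay over Hectd4 (124 kb), Fry (120 kb), Mdn1 (114 kb), the gamma protocadherin cluster annotated as Gm37013 (109 kb), Zzef1 (108 kb), Cep350 (105 kb), Smarcc1 (105 kb), Cplane1 (104 kb) and Ubr4 (101 kb). Mdn1 is a ribosome assembly ATPase, Cep350 a centrosomal protein, Smarcc1 a subunit of BAF chromatin remodelling complexes, Cplane1 a ciliogenesis factor and Ubr4 a ubiquitin ligase. Joining across 10 kb lengthened the longest domain to 294 kb and left 11309 domains, and joining across 1 kb gave 36640.

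At least 10% of the span was covered by replicated peaks in 6895 of 21938 protein-coding genes (31.4%), against 30.2% ± 4.34 (SD, n = 2) with each replicate's own peaks, 7307 genes in replicate 1 and 5960 in replicate 2. At least 1 bp was covered in 10073 genes (45.9%), and at least 50% of the span in 1808 (8.24%), but in 1544 with the own peaks of replicate 1 and 686 with those of replicate 2. Marked genes had a median covered share of 34.4%. The share of genes marked depended on length. Among 10 groups of equal size ordered by length it was 7.06% in the shortest, 45.8% in the seventh and 14.4% in the longest.

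Of the 34 gene lists, 8 were marked more often than other genes and 17 less often, and 9 did not pass the threshold (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the lists). These tests compare genes within the pooled tissue and say nothing about variation between animals. Permutation within groups of similar gene length gave 8 higher and 18 lower. Adjusted p values below are from Fisher's exact test, and the ranges over alternatives also take in that permutation.

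Genes of the basic machinery of the cell were marked more often than other genes. Of the 31 proteasome genes, 30 were marked (adjusted p = 1.46e-13, Fisher's exact test), with a median covered share of 53.0%. Psmc1 and Psmc4, ATPases of the regulatory particle, had 74.2% and 71.3%, Psma2 had 20.1%, and Psmd14 was the single unmarked member at 2.33%. Of the 24 spliceosome genes 23 were marked (adjusted exact p = 2.55e-10), led by Sf3b3 with 89.4% and Sf3a1. Srsf2, a short splicing factor gene, had 8.89% (21.6% in replicate 1 and 6.79% in replicate 2), and Snrpd1 had 21.9%. Of the 24 genes of RNA polymerase II and its elongation factors 22 were marked (adjusted exact p = 5.61e-09). Leo1, a subunit of the PAF1 complex, had 75.2% and Polr2b, the second largest polymerase subunit, 74.9%, while the short subunit genes Polr2k and Polr2i held no peak. Of the 55 ribosomal protein genes 46 were marked (adjusted exact p = 1.83e-14), led by Rps3 with 75.2% and Rpl5 with 74.3%, and the 1.26 kb Rplp1 and 2.32 kb Rpl10 had no replicated peak. Sf3b3, Polr2b, Rpl5, Psma2 and Srsf2 overlap another protein-coding gene, so part of their coverage can belong to that neighbour.

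**Figure D4:**
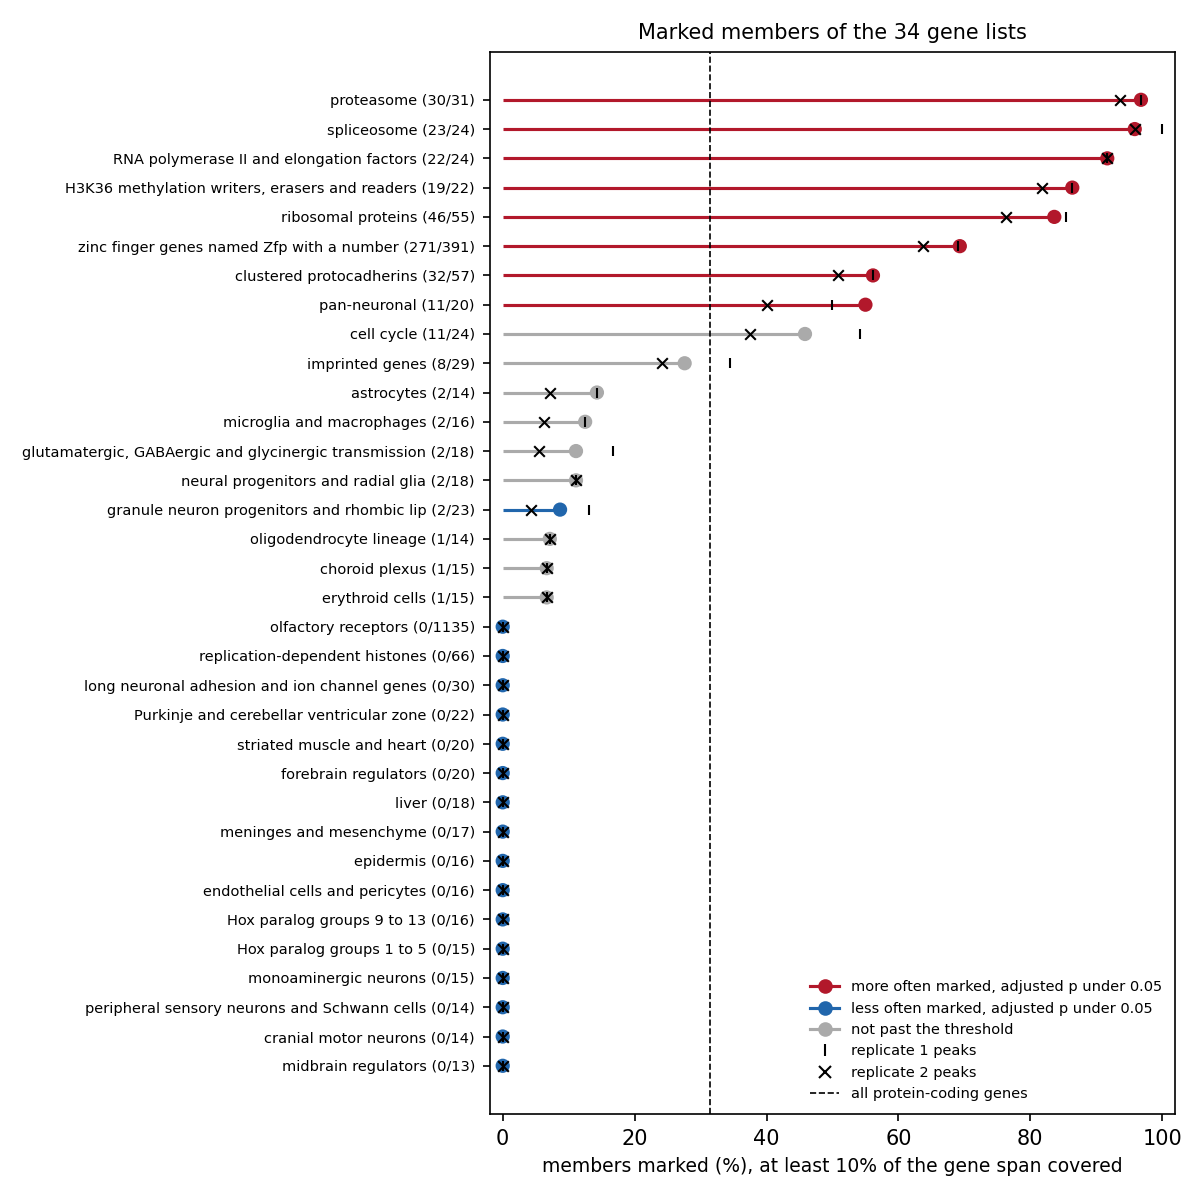
Share of members marked (x axis, %; at least 10% of the gene span covered by replicated peaks) in each of 34 gene lists, with the number marked and the number of members in each name; filled circles are the replicated peaks, bars and crosses the own peaks of replicate 1 and replicate 2, and the dashed line all protein-coding genes at 31.4%. Red lists were marked more often and blue lists less often than other genes (adjusted p under 0.05, Fisher's exact test), from 30 of 31 proteasome genes to 0 of 1135 olfactory receptors.

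The genes that write, erase and read H3K36 methylation were themselves marked, 19 of 22 (adjusted p = 6.27e-07, Fisher's exact test). Among the writers, Nsd1 was covered over 52.3%, Nsd2 over 44.3%, Ash1l over 39.1%, Setd2 over 38.7% and Nsd3 over 33.0%. Setmar had 10.7%, with 13.4% in replicate 1 and 7.18% in replicate 2. Among the demethylases, Kdm4a had the highest share of the list with 81.9% (74.4% ± 8.06, n = 2), Kdm2a had 35.8%, Kdm4b 28.6% and Kdm4c 15.8%, and Kdm2b was unmarked at 5.69%. Readers included Brpf1 (68.8%), Psip1 (65.9%), Brd1 (58.1%), Mtf2 (46.7%), Morf4l1 (44.8%), Msh6 (41.2%), Phf1 (27.3%) and Zmynd11 (12.9%). The DNA methyltransferase Dnmt3a, a PWWP domain reader, had 23.6%, its paralog Dnmt3b no replicated peak, and Phf19 no peak in any file. Nsd2, Ash1l, Kdm2b, Psip1, Mtf2, Msh6 and Phf1 overlap another protein-coding gene, so part of their coverage can belong to that neighbour.

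Genes shared by all neurons were marked more often than other genes, by a narrow margin. Of 20 pan-neuronal genes 11 were marked (adjusted p = 0.0404, Fisher's exact test) and all 20 held at least 1 bp of peak. Atp1a3, the neuronal sodium pump, had 73.3% and Ina, an intermediate filament gene that overlaps Nt5c2, 44.1%. Rbfox3, 422 kb long, had 0.159% and Syt1, 513 kb long, 0.359%. This call was lost in 9 of 14 alternatives, including the own peaks of replicate 2 (adjusted exact p = 0.224) and of replicate 1 (adjusted p = 0.167), with adjusted p from 8.34e-07 to 0.317 over all 14.

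Regulators and other markers of the hindbrain's own lineages were marked less often than other genes in each list that passed. None of 22 Purkinje and cerebellar ventricular zone genes was marked (adjusted p = 1.02e-03, Fisher's exact test). Ebf3 and Bcl11a had 1.49% and 1.48%, and the long genes Grid2 and Dab1 no replicated peak. Of 23 genes of granule neuron progenitors and the rhombic lip 2 were marked (adjusted exact p = 0.0312). These were Ptch1, the Sonic hedgehog receptor, with 35.4% (27.7% ± 9.39, n = 2) and Mycn with 11.1% (10.1% in replicate 1 and 4.43% in replicate 2), while Gli2 and Lmx1a had no replicated peak. That call was lost with the own peaks of replicate 1 (adjusted exact p = 0.0565), where 3 of 23 were marked, and in 2 other alternatives, with adjusted p from 0.0116 to 0.225. None of 15 monoaminergic genes (adjusted exact p = 8.10e-03) and none of 14 cranial motor neuron genes (adjusted p = 0.0116) was marked, and Tph2, which makes serotonin, and Chat, which makes acetylcholine, held no peak in any file. No replicated peak touched any of the 15 genes of Hox paralog groups 1 to 5, which pattern the hindbrain (adjusted exact p = 8.10e-03). Hoxd3 alone among them had a peak in a single replicate, over 1.03% of its span in replicate 1. The call of Hox groups 1 to 5 was lost among genes of at least 5 kb (adjusted exact p = 0.1199) and without genes that overlap another (adjusted p = 0.160), with 6 and 8 members left and 0% marked in both. That of cranial motor neurons was lost in 2 of 14 alternatives, also at 0%.

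Progenitor, transmitter and cell cycle genes did not pass the threshold with the replicated peaks. Of 18 genes of neural progenitors and radial glia 2 were marked (adjusted p = 0.0884, Fisher's exact test). Msi1 had 35.1% and Vim 31.3%, and Rfx4 and Pax3 no replicated peak. Of 18 genes of glutamatergic, GABAergic and glycinergic transmission 2 were also marked (adjusted exact p = 0.0884), Grin1 with 37.8% and Slc6a1 with 17.1%. Slc6a1 had 19.9% in replicate 1 and 7.20% in replicate 2. Slc17a7 and Glra2 had no replicated peak, yet 15 of the 18 genes held some peak. Counting genes with 1 bp of peak turned the transmission list round, to 83.3% (adjusted exact p = 2.62e-03), and with the own peaks of replicate 2 it passed as marked less often (adjusted p = 0.0486), over a range up to 0.340. The 1 bp test was not matched on gene length. Over all genes the median covered share was 0% in the shortest of 10 length groups, 5.80% in group 7 and 0.416% in the longest. The transmission list had a median length of 62690.5 bp, which lies in group 9 (58120 to 109912 bp). Genes of group 9 had a median covered share of 3.55% and 36.8% were marked. The transmission list had a median covered share of 1.69% and 11.1% were marked. Of 24 cell cycle genes 11 were marked (adjusted exact p = 0.142). Cdk4, which overlaps Tspan31, had 69.4% and Rrm1, a ribonucleotide reductase subunit, 56.0%, while Bub1b and Top2a had no replicated peak. The progenitor list passed as marked less often at a covered share of 5% (adjusted exact p = 0.0309, over a range up to 0.394), and the cell cycle list as marked more often with 1 bp of peak (70.8%, adjusted p = 0.0269, over a range up to 0.657).

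Markers of regions outside the hindbrain were unmarked, as were several lists of the hindbrain itself. A share of 0% therefore does not separate regions, and Gata2 stood in both the midbrain and the monoaminergic list. None of 20 forebrain regulators (adjusted p = 2.54e-03, Fisher's exact test) and none of 13 midbrain regulators (adjusted p = 0.0194) was marked, with Lhx2, Lhx8, Dmbx1 and Wnt8b at 0% and Satb2 at 0.123%. None of the 16 genes of Hox groups 9 to 13, which pattern the caudal body, held a replicated peak (adjusted exact p = 8.10e-03), including Hoxa10 and Hoxc9. With 0% marked in each case, the midbrain call was lost in 3 of 14 alternatives (adjusted exact p 7.14e-04 to 0.0704) and that of Hox groups 9 to 13 among genes of at least 5 kb (adjusted p = 0.0796, over a range from 1.50e-04).

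Markers of other cell types that dissected hindbrain can hold were marked rarely. No member was marked among 16 genes of endothelial cells and pericytes (adjusted p = 8.10e-03, Fisher's exact test), 17 of meninges and mesenchyme (adjusted p = 6.07e-03) or 14 of peripheral sensory neurons and Schwann cells (adjusted p = 0.0116). Of these, Pdgfrb had 1.99%, Tek 0.243% and Scn9a 2.73%, and Erg, Flt1, Aldh1a2, Prrx1, Runx1 and Scn10a had no replicated peak. Lists of tissues outside the nervous system were also unmarked, with 0 of 18 liver genes (adjusted exact p = 3.81e-03), 0 of 20 of striated muscle and heart (adjusted p = 2.54e-03) and 0 of 16 of epidermis (adjusted p = 8.10e-03). Ttn had 4.66%, and Ryr1, Mb, Cps1, Hnf4a, Trp63 and Dsc3 had no replicated peak. The call of peripheral sensory neurons and Schwann cells was lost in 2 of 14 alternatives at 0% marked, with adjusted exact p from 4.14e-03 to 0.0703.

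Glial, immune, blood and choroid plexus markers did not pass the threshold of Fisher's exact test with the replicated peaks, and some of their marked members overlap or adjoin another marked gene. Of 14 oligodendrocyte lineage genes 1 was marked (adjusted p = 0.0894, Fisher's exact test), namely Cnp with 56.3%, which overlaps Dnajc7 (41.1%). Myrf had 4.84%, and the myelin genes Mbp and Ugt8a no replicated peak. Of 14 astrocyte genes 2 were marked (adjusted exact p = 0.258). Glul, the glutamine synthetase gene, had 55.2% and overlaps the unmarked Teddm2. Atp1b2 had 27.3% (30.7% in replicate 1 and 3.25% in replicate 2) and lies 7862 bp from Trp53 (23.8%). Aldh1l1 and Aqp4 held no peak. Of 16 microglia and macrophage genes 2 were marked (adjusted exact p = 0.185). Cd68 had 96.2% over its 1.94 kb and lies 782 bp from Eif4a1 (53.3%). Cx3cr1, annotated over 168 kb, had 12.4% (13.1% in replicate 1 and 8.74% in replicate 2) and overlaps Wdr48 (56.6%). Adgre1 and Ptprc held no peak. Of 15 erythroid genes 1 was marked (adjusted exact p = 0.0608), the transferrin receptor gene Tfrc with 60.2%, which lies 11079 bp from Tnk2 (20.2%), while Epb42 had 1.94% and Alas2 and Gata1 no replicated peak. Of 15 choroid plexus genes 1 was marked (adjusted exact p = 0.0608), Kcnj13 with 26.5%, which overlaps Gigyf2 (36.9%). Trpm3 had 0.817%, and Htr2c and Prlr no peak. The choroid plexus list passed as marked less often in 7 of 14 alternatives and the erythroid list in 5, both with the own peaks of replicate 1 among them (adjusted exact p = 0.0380), over ranges of 0.0191 to 0.207 and 0.0191 to 0.475. The oligodendrocyte list passed as marked less often in 2 alternatives, the length-matched permutation (adjusted p = 0.0497) and a covered share of 5% (adjusted p = 0.0292), over a range up to 0.257. The microglia list did so in 1, without the first 1 kb of each gene (adjusted exact p = 0.0367), over a range up to 0.413.

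Among gene families, numbered zinc finger genes were marked far more often than other genes and olfactory receptors not at all. Of 391 Zfp genes 271 were marked (69.3%, adjusted p = 7.31e-53, Fisher's exact test), 270 with the own peaks of replicate 1 and 249 with those of replicate 2. Zfp869 had 94.7% and Zfp110 87.3%, and the long genes Zfp804b and Zfp697 no replicated peak. None of 1135 olfactory receptors held a replicated peak (adjusted exact p = 3.35e-191), Olfr56 and Olfr643 included. None of 66 replication-dependent histone genes did (adjusted exact p = 1.43e-10), such as Hist1h2be and Hist1h2bc. With a median length of 537 bp, the histone call was lost among genes of at least 5 kb (adjusted exact p = 0.592) and without the first 1 kb of each gene (adjusted p = 0.0685), over a range from 2.67e-17. Only 3 and 8 members were left in these, with 0% marked as before, and the length-matched permutation kept the call (adjusted p = 8.40e-03, 8.75% expected). Of 57 clustered protocadherins 32 were marked (adjusted exact p = 4.88e-04), Pcdhga2 with 45.6% and Pcdhga3 with 45.4%, and Pcdhb16 and Pcdhb18 had no replicated peak. All 57 overlap other protein-coding genes and those of the alpha and gamma clusters share constant exons, so their shares are not separate measurements. Their call was lost at a covered share of 20% (adjusted exact p = 0.373) and with the stronger peaks by fold (adjusted p = 0.0775), over a range from 5.19e-07.

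Of 29 imprinted genes 8 were marked, a share close to that of other genes (27.6%, adjusted p = 0.842, Fisher's exact test). With 1 bp of peak 65.5% of them counted (adjusted exact p = 0.0468, against up to 1 in other alternatives). Nap1l5 and Nnat, short genes inside Herc3 and Blcap, had 67.1% and 57.1%, and Rasgrf1 and Plagl1 no replicated peak. None of 30 long neuronal adhesion and ion channel genes was marked (adjusted exact p = 5.64e-05), although 22 held some peak. Cacna1c had 5.52% and Dscam 3.15%, and Lsamp and Cdh12 no replicated peak. Counting any gene with 1 bp of peak turned this comparison round, to 73.3% of the list (adjusted exact p = 4.34e-03, against 1.30e-05 to 0.0279 in other alternatives). That test was not matched on gene length, and the shortest member was 520 kb long.

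Genes on the X chromosome were marked much less often than autosomal genes. Of 948 X genes 75 were marked (7.91%), against 6820 of 20807 autosomal genes (32.8%), an odds ratio of 0.176 (p = 3.15e-72, Fisher's exact test, two-sided). Autosomes ranged from 25.2% on chromosome 14 to 41.0% on chromosome 8, and none of 183 Y genes was marked. Over the alternatives the share of X genes lay between 3.16%, with the stronger peaks by fold, and 24.1%, with 1 bp of peak, and was 4.85% with the own peaks of replicate 2 and 9.70% with those of replicate 1. It stayed below that of autosomes in each. The tissue pooled male and female embryos, so active and inactive X chromosomes were measured together. The test did not match genes on length, and no cause of the lower share was tested.

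The replicates differed mainly in how much of each gene was covered. With each replicate's own peaks, 5903 genes were marked in both, 1404 in replicate 1 alone and 57 in replicate 2 alone. With 1 library per side this difference has no test. Among genes of at least 5 kb, the largest excess in replicate 1 was in Acadvl, a mitochondrial acyl-CoA dehydrogenase, with 62.2% against 15.4%, followed by the kinase gene Mapk7 (63.5% against 18.4%) and the mitochondrial carrier gene Slc25a10 (45.6% against 6.49%). The largest excesses in replicate 2 were in Polr2g (53.6% against 38.6%), Tmem177 (14.9% against 0%) and Btf3 (56.5% against 42.2%). Of the 270 numbered Zfp genes marked in either replicate, 21 were marked in replicate 1 alone (7.78%), against 19.5% of other such genes (adjusted p = 3.75e-06, Fisher's exact test, over genes and not libraries, among the lists with a member marked in either replicate). The median covered share of all Zfp genes, 28.2% in replicate 1 and 19.8% in replicate 2, lay above the 10% that calls a gene marked. No list passed among genes marked in replicate 2 alone. Taking equal numbers of the strongest peaks left 1052 genes in replicate 1 alone and 216 in replicate 2 alone, and a covered share of 20% left 1438 and 36. Taking the strongest peaks of replicate 1 up to the length that replicate 2 covers, an alternative chosen after the difference was seen, turned it round, to 362 and 503, but evens out the counts by construction.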

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

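The test of equal covered length, the test of the Zfp genes against the highest length-matched list and the comparison with olfactory receptors were chosen only after the result was seen, and the other tests below, with the length-matched permutation of each list, were set earlier.

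Some signal lay in sequence that the gene comparisons did not use. On scaffolds outside the chromosomes there were 44 replicated peaks (80 in replicate 1 and 45 in replicate 2). There were 23 domains of at least 10 kb that touch no protein-coding gene. Several lay in the imprinted noncoding genes of chromosome 12, with Meg3 covered over 61.0% of its 35.8 kb domain (49.9% in replicate 1 and 39.9% in replicate 2), Mirg over 60.4% of 32.8 kb (57.6% and 33.2%), B830012L14Rik over 55.8% of 24.8 kb (46.6% and 37.5%) and Rian over 31.9% of 10.2 kb (33.4% and 16.5%). Another, over 42.6% of 13.3 kb on chromosome 10, lay in Rmst, a long noncoding RNA gene of neural development (44.2% in replicate 1 and 23.2% in replicate 2). The longest, 46.3 kb on chromosome 17 from 22768729 to 22815009, overlapped the pseudogene AC154486.3. These genes were named after their values were seen.

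More genes were marked in replicate 1 alone than in replicate 2 alone, 1404 against 57. The number of peaks does not account for all of this, since with equal numbers of the strongest peaks the ratio fell from 24.6 to 4.87. In that setting replicate 1 still covered 51.2 Mb and replicate 2 39.6 Mb. At equal covered length, 60.9 Mb each, the ratio was 0.720, but this setting evens out the counts by construction, so whether the covered length is the cause stays open. The difference in covered share also rose with the GC share of the gene, with a Spearman's rho of 0.272 across 5391 genes at equal numbers of peaks and 0.203 across 6322 genes at equal covered length, so a GC-dependent recovery may contribute. The files taken to be controls, 2 for replicate 1 and 1 for replicate 2, cannot be separated from the replicate. Depth is unknown, and no biological explanation was tested.

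Numbered Zfp genes were marked in 69.3% of cases. Gene length does not account for this, as the highest share among 10000 length-matched lists was 47.3%. Of the Zfp genes with no other numbered Zfp gene within 500 kb, 63.4% were marked, an odds ratio of 3.90 (95% interval 2.67 to 5.77). This argues against reads shared with numbered Zfp neighbours alone. Zinc finger genes under other names and pseudogenes were not counted as neighbours, so reads shared with those cannot be judged. Paralog families differed, since olfactory receptors had an odds ratio with an upper 95% bound of 0.00657, while clustered protocadherins were marked more often than other genes, with an odds ratio of 2.80. All 57 protocadherins overlap other protein-coding genes, and 1 domain lay over 21 coding genes of the gamma cluster. That odds ratio of 2.80 therefore counts the same peaks more than once. Not every large family gives peaks, but reads shared with distant paralogs or with those under other names stay open, and no biological explanation was tested.

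None of the 30 long neuronal adhesion and ion channel genes, of 520 to 2271 kb, was marked. Gene length may account for this, since 41.0% of lists matched on the nearest lengths also had no marked member and the median covered share of the list, 0.152%, lay at percentile 97.3 of such lists. The lists matched on the nearest lengths had a mean of 2.96% marked. Against the coarser match within 10 groups of gene length the list was still marked less often (adjusted p = 0.0279, permutation, 14.4% expected). That match cannot decide the question, since its longest group runs from 109945 to 4434882 bp. The members did hold signal below the 10% threshold, with a median of 11 pooled peaks per gene against 3 in the matched lists, at percentile 99.8. No biological explanation was tested.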

How the results depend on the processing

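Some tests were chosen only after the result was seen. They were those of equal covered length, the last 50% of the gene and peaks that overlap a peak of each replicate by 50%. Placement inside genes, peak counts without scaffolds and the background without chemosensory receptors were also chosen then. So were the test of the Zfp genes against the highest length-matched list and the comparison with olfactory receptors. Peak numbers, the Jaccard index, the count of marked genes (4752 to 10073) and the lower share on X kept their direction in the alternatives run. Of 475 pairs of a list and an alternative, 428 kept direction and side of the threshold, 26 lost the call, 18 gained one and 3 reversed, and 15 of the 25 lists past the threshold kept it in every alternative run. The reversals came with 1 bp of peak, for transmission genes (adjusted exact p = 2.62e-03), imprinted genes (adjusted p = 0.0468) and long neuronal genes (adjusted p = 4.34e-03). These 1 bp tests were not matched on gene length. With 1 replicate at a time, gene bodies held 94.5% to 94.9%, exons 19.05% to 19.8%, and the last of 10 parts of the gene was covered 12.99 to 14.4 times as much as the first. With the pooled peaks these were 94.5%, 18.8% and 12.7, and with the stronger peaks by fold 95.6%, 20.985% and 18.7, with 0.365% in promoters. Promoters of 2 kb held 1.29%. The ratio along the gene was 15.5 with peaks overlapping each replicate and 9.32 in genes of at least 20 kb, and that of exons to introns was 1.22 in the last 50% of the gene. Gaps of 1 kb gave 36640 domains, and gaps of 10 kb gave 11309 with a longest of 294 kb. Genes marked in replicate 2 alone numbered 36 at a covered share of 20% and 216 with equal numbers of peaks. At equal covered length 362 were marked in replicate 1 alone and 503 in replicate 2 alone. Causes were weighed above only for the difference between the replicates, the numbered Zfp genes and the long neuronal genes, and no other cause was tested. Depth is unknown, so an absent peak does not show an absent mark.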

Other observations

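The values below are given without tests, and the comparisons were chosen only after the result was seen.

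Marked numbered Zfp genes had a steeper profile than other marked genes. Over 262 marked Zfp genes of at least 5 kb, replicated peaks covered 2.02% of the first of 10 parts and 58.6% of the last, a ratio of 29.0. Over 6053 other marked genes the values were 3.76% and 52.4%, a ratio of 13.9. Zfp genes reached their highest share, 68.3%, in the ninth part, against 56.1% in other genes. The difference was not tested.

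In the 890 isolated marked genes, coverage in the last 500 bp was lower than on either side in both replicates. It was 28.1% in replicate 1 and 21.4% in replicate 2, against 33.5% and 23.9% in the first 500 bp past the end.

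The difference between the replicates rose with GC across 5 groups of genes at equal numbers of peaks. The mean excess of replicate 1 was 3.49 percentage points in the group with the lowest GC, then 5.23, 6.37 and 8.41, and 9.79 in the group with the highest.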
